A study of Drosophila melanogaster with 2 samples.

How the data were processed

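Chromatin immunoprecipitation with sequencing was done on whole embryos aged 0 to 8 h from transgenic flies carrying an eGFP fusion of CG10959, with an antibody against GFP, and chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels name 2 biological replicates of 1 group and no other condition. Controls named by the labels were not analysed here.

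The authors' peak lists were used as deposited. Per the descriptions deposited with them, they are narrowPeak lists on the dm6 assembly, each made from an alignment of the sample and one of a control, as a ranked list and an IDR thresholded list for each replicate and for the pooled replicates, with a conservative pooled version. IDR, the irreproducible discovery rate, measures how consistently a peak ranks between sets of reads. The aligner, the peak caller and their versions are not given in the sources used here. The signal deposited for each peak is the authors' strength of the peak relative to the control, on a scale not given in the sources used here, so signals were compared only within a list, or between the replicates as a correlation. The score deposited with each peak is a whole number, and in the ranked lists it equalled the authors' IDR on a log scale, up to 1000, to within 1.1 units. The deposited −log10 of the IDR was used only for this check. Scores in every thresholded list were 830 or more, an IDR of about 0.01. Every main-list peak was in its ranked list, and 115 ranked peaks with such a score were left out of the thresholded list. The descriptions name a further region file among the sources of the thresholded lists. A total of 16 columns of per-replicate values in the pooled ranked lists were not used, because no label ties them to a replicate. Since no counts were used, depth is unknown, and intervals cover sampling of peaks or genes only.

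The main list was the pooled IDR thresholded list. Its peaks on X, 2L, 2R, 3L, 3R and 4 were placed on the Ensembl annotation of the same assembly, and sequences were read from the RefSeq copy of that assembly. Each summit took the first class that held it among promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. TSSs of transposable elements and pseudogenes were left out. Coordinates are 1-based on dm6.

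Tests, samples, gene lists, motifs and the rule for named genes were fixed before the data were examined. Overlap of replicates was tested with 1000 shuffles within chromosomes, and annotation classes against 1000 draws of random positions on the same chromosomes. Arms were compared by an exact binomial test, 28 gene lists by Fisher's exact test, and 19 motifs and 8-mers by an exact McNemar test of the 50 bp on each side of the summit against a flank 300 bp away on a side drawn at random. The 8-mers were ranked on 2L and 2R and the first 10 were tested on 3L, 3R and X. Median signals were compared with 100000 resamples and GC content with 10000 sign flips. Tests were two-sided except the overlap, and p was adjusted by Benjamini and Hochberg within each family, with a threshold of 0.05. Symbols of 9 listed genes were updated to the annotation. Named genes were CG10959, the gene with the nearest TSS for the 20 strongest peaks in both replicates, up to 4 members of each list that passed and up to 2 of each developmental list that did not, by signal of the promoter peak. The peak in ey, the peaks of the mitochondrial ribosomal protein list, the peaks beside CG10959 and the peaks left out of the main list were named after their values were seen.

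The comparison of GC content, the 4 signal groups, the GC-matched background, the peaks in both replicates' lists and the merging of close peaks were added after the data were seen. Alternatives covered the conservative list, the strongest 500 peaks, each replicate's own list, other promoter distances, other overlap rules and other backgrounds. The tests were checked on simulated data of 3417 peaks. At random positions no class, motif or 8-mer passed. With some positions moved to TSSs, 39.7% were expected at promoters, given the share measured before the move, and 39.7% were measured. A planted overlap of 61.0% was measured as 61.8%. A planted 8-mer ranked first. The seed was 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.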

Results

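CG10959 is a Drosophila gene on the X chromosome whose product was tagged with green fluorescent protein. Chromatin of whole embryos aged 0 to 8 h was immunoprecipitated with an antibody against the tag and sequenced, which gives a map of the DNA regions where the tagged protein, or a complex holding it, was crosslinked. The labels put both libraries in 1 group, as biological replicates 1 and 2, and name no second condition, so the comparisons are between the replicates, and between bound regions and the rest of the genome. Replicate 1 had 2065 peaks past the authors' reproducibility threshold and replicate 2 had 2341. The pooled list, called the main list here, held 3434 peaks, of which 3417 lay on the arms X, 2L, 2R, 3L, 3R and 4 of the dm6 assembly and entered the comparisons. Read numbers per library are not given in the sources used here, so the depth behind each peak is unknown. Each peak's signal is the authors' own value in their units. It is used to rank and describe peaks, to compare them within a list and, as a correlation, to compare the replicates.

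The strongest peaks lay mostly at promoters. Of the 20 strongest main-list peaks found in both replicates, 17 had a summit within 500 bp of a transcription start site (TSS), 2 lay in introns and 1 was intergenic. The strongest had a signal of 1924.84 and lay at X 2137187 to 2137519, with its summit 500 bp upstream of a TSS of ph-p (FBgn0004861), which encodes a Polycomb group protein. The next lay at 3L 19590441 to 19590775, 97 bp upstream of CG14100 (FBgn0036889), with a signal of 1916.7, and at X 2703714 to 2704037, 37 bp upstream of Ugalt (FBgn0024994), a UDP-galactose transporter gene, with a signal of 1776.72. A peak at 3L 22878734 to 22879056, 99 bp downstream of the TSS of Chro, which encodes the interband protein Chromator, had a signal of 1486.25.

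The other promoter peaks among the 20 were nearest to px, Art3, CG11964, CHMP2B, CG13921, CG7601, CenG1A, CG1888, lncRNA:CR44339, Fkbp14, mRpL41, CG9147 and CG5611. The intronic ones lay in CG11050, at 2L 6612533 to 6612894, and in Adf1, a gene of a transcription factor with a Myb-type domain, at 2R 6662899 to 6663208. The intergenic one lay at 2L 2202254 to 2202564, 3760 bp from the TSS of CG31668. Signals of the 20 ranged from 1182.4 to 1924.8. As an example of the sequence, the 31 bases centred on the summit at Art3 (3R 15229376 to 15229696) read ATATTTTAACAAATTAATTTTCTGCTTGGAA.

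CG10959 itself had no main-list summit within 500 bp of its TSS. The gene spans X 8148783 to 8150686 on the plus strand, and main-list peaks lay on both sides of it. One at X 8147982 to 8148341 had a signal of 97.9665 and its summit 621 bp before the gene, and it was nearest to the TSS of CG15336. One at X 8151133 to 8151492 had a signal of 109.901 and its summit 627 bp beyond the gene, in a coding exon, nearest to the TSS of Gbeta5. Farther out, stronger peaks lay at the promoters of CG17982 (X 8143590 to 8143949, signal 239.3, 5013 bp before the gene) and Traf6 (X 8157244 to 8157603, signal 154.6, 6738 bp beyond it). Ranked peaks within 10 kb of the gene's midpoint had a median signal of 40.6, where the middle value around the other protein-coding genes of the X chromosome was 24.1.

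The replicates shared most of their peaks. Of the 2043 replicate 1 peaks on the arms, 1590 (77.8%) overlapped a replicate 2 peak by at least 1 bp, and of the 2328 replicate 2 peaks, 1588 (68.2%) overlapped a replicate 1 peak. Peaks shuffled within their chromosome overlapped 20.7 times on average and at most 38 times in 1000 shuffles (one-sided permutation test, p = 0.001, the smallest that 1000 shuffles can give). Summits of overlapping peaks lay a median of 19 bp apart. Across the 1590 overlapping peaks the signals of the replicates had a Spearman correlation of 0.798 and a Pearson correlation of 0.741 on the log2 scale. These are correlations across peaks, which are not independent replicates, so no p is given. Of these pairs, 34 had a replicate 1 signal under 20 and 1 had a replicate 2 signal under 20. Each replicate 1 peak was paired with the strongest replicate 2 peak that overlapped it. A weak replicate 1 peak could thus be set against a strong peak with another summit, and the 34 pairs do not show disagreement at a site. With summits within 100 bp, the Pearson correlation was 0.870 over 1514 pairs.

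**Figure D1:**
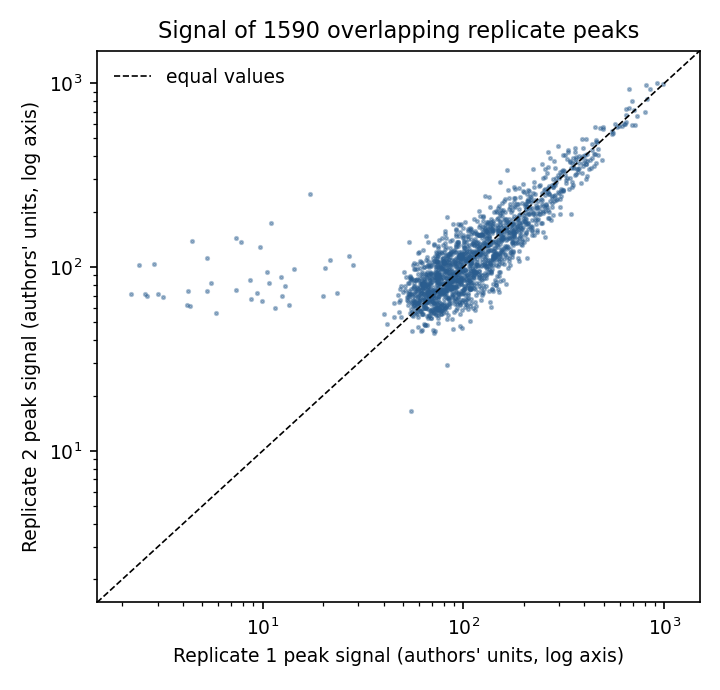
Each point is 1 of 1590 overlapping peak pairs, with the replicate 1 signal on the x axis and the replicate 2 signal on the y axis, both in the authors' units on log axes, and the dashed line marks equal values. Most pairs lie along the line, and 34 pairs with a replicate 1 signal under 20 lie apart on the left. Each replicate 1 peak is paired with the strongest replicate 2 peak that overlaps it. The line is only a guide, since the scale of the signal is not given in the sources used here.

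Support by the single replicates went with signal. Of the 3417 main-list peaks, 1600 (46.8%) overlapped a peak in both replicates' own lists, with a median signal of 206.9. Another 370 overlapped a peak of replicate 1 only and 560 of replicate 2 only. The remaining 887 (26.0%) were in neither replicate's list and had a median signal of 87.3. The conservative pooled list held an overlapping peak for 2849 (83.4%) of the 3417. With the main list split by signal into 4 groups of equal size, 6.55% of peaks in the weakest group were in both replicates' lists, against 98.2% in the strongest.

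Peaks were concentrated at promoters and sparse in exons. Promoters, the 500 bp on either side of a TSS, held 1336 of the 3417 summits (39.1%, 95% Wilson interval 37.5 to 40.7) against 13.5% ± 0.58 (SD over 1000 draws) of random positions on the same chromosomes, a 2.91-fold difference. Coding exons held 3.66% against 13.7%, 3' UTRs 0.673% against 4.40%, and 5' UTRs outside promoters 0.410% against 0.768%. Introns held 35.4% against 39.3% and intergenic DNA 19.9% against 27.6%. Each of these 6 differences passed a two-sided permutation test with an adjusted p of 0.0117 for 5' UTRs and 0.0028 for the others, where 1000 draws allow no unadjusted p below 0.002. Non-coding exons did not pass (0.936% against 0.758%, permutation test, adjusted p = 0.288). The class shares add up to a fixed total, so the excess at promoters lowers the shares of the other classes. No test compared summits and random positions outside promoters on their own, so the lower shares of introns and intergenic DNA do not show avoidance. Of the 2081 summits outside promoters, 1208 lay in introns and 679 in intergenic DNA. Introns were a larger part of the summits outside promoters than of the random positions outside promoters, a difference that was not tested.

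**Figure D2:**
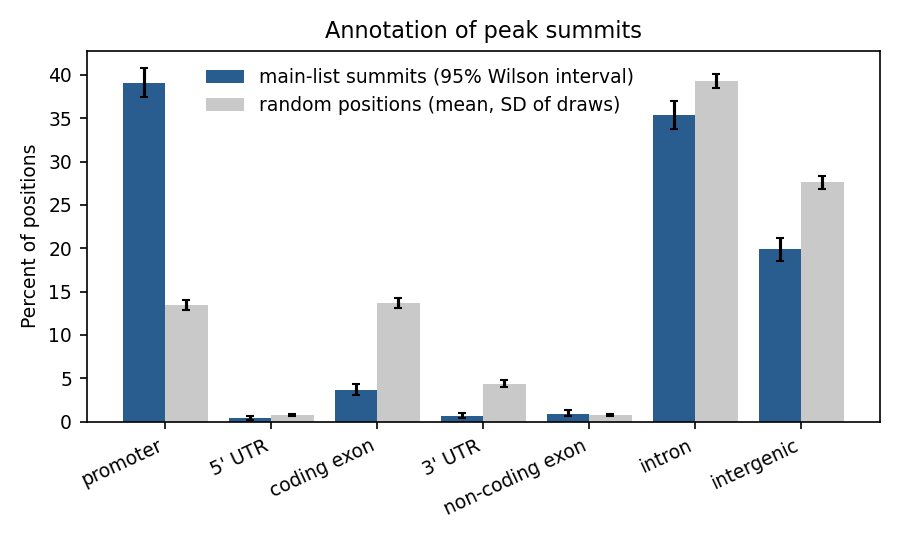
Bars give the percent of positions in each annotation class, in blue for the 3417 main-list summits with 95% Wilson intervals and in grey for random positions on the same chromosomes with the SD of 1000 draws. Promoters held 39.1% of summits and 13.5% of random positions.

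Promoter peaks were also stronger. Their median signal was 142.6 (quartiles 98.9 and 244.6, 1336 peaks), against 115.6 (89.8 and 178.0, 2081 peaks) for all other peaks, a difference of 26.95 (two-sided permutation test, 100000 resamples, p = 1e-05, the smallest they can give). Among the strongest 500 peaks the difference was 22.7 and did not pass the permutation test (p = 0.168). In the replicates' own lists it was 9.69 for replicate 2 and 15.1 for replicate 1, in the units of those lists. The promoter share was 51.2% in the strongest of the 4 signal groups and 29.2% in the weakest.

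The small chromosome 4 was almost free of peaks. It held 1 peak, at 709708 to 710067 in an intron of ey, the eyeless gene, where 34.4 were expected from its length (exact binomial test, adjusted p = 3.78e-13). Its density was 0.0291 times the expected, and 0.0853 times in the list of replicate 2 (2 peaks) and 0.0486 times in that of replicate 1 (1 peak). The large arms differed little. Densities were 1.10 times the expected on 2L (659 peaks, exact binomial test, adjusted p = 0.0139), 1.11 times on 3L (793 peaks, exact binomial test, adjusted p = 0.00524) and 0.908 times on 2R (586 peaks, exact binomial test, adjusted p = 0.0139), while X (580 peaks) and 3R (798 peaks) did not pass. The value on 3L turned to 0.914 times among the strongest 500 peaks, and it did not pass in either replicate's own list. In those lists 3R passed, at 0.885 times for replicate 1 and 0.914 times for replicate 2 (exact binomial test, adjusted p = 0.00798 and 0.0297), and X passed for replicate 1 alone, at 1.11 times (exact binomial test, adjusted p = 0.026). Among main-list peaks found in both replicates' lists, X was at 1.15 times and 3R at 0.876 times (exact binomial test, adjusted p = 0.00869 for both). Lengths of the arms were taken whole, including repeats in which few reads can be placed. Peaks with a passing score that the main list leaves out were uneven over the arms, with 42 of 84 on 3R and 6 on X. The lists of replicates 1 and 2 left out 59 and 70 such peaks on the arms. Densities were not recomputed with these peaks, so the values on 3R and X hold only for the lists as deposited.

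Ribosomal protein genes and genes of chromatin architecture carried promoter peaks more often than other genes. Of 13945 protein-coding genes on the arms, 1569 (11.3%) had a main-list summit within 500 bp of a TSS. Among cytoplasmic ribosomal protein genes 41 of 92 had one (44.6%, 95% Wilson interval 34.8 to 54.7, 4.04-fold, Fisher's exact test, adjusted p = 1.62e-14). The strongest were at RpS27 (signal 447.1), RpL7 (386.8), RpL32 (351.9) and RpL23A (314.6). Among insulator and architectural protein genes 9 of 17 had one (52.9%, 31.0 to 73.8, 4.73-fold, Fisher's exact test, adjusted p = 0.000138). These were led by Chro (1486.2), Cp190 (470.3), su(Hw) (304.5) and pzg (304.2), and CG10959, itself on that list, had none. With each peak given to its nearest gene at any distance, 5 of the 17 had a peak and the list did not pass (1.98-fold, Fisher's exact test, adjusted p = 0.225). In the promoter tests any annotated TSS of a gene counted. Genes with more TSSs thus had more promoter DNA, which was not adjusted for. The other genes in these tests were protein-coding genes, also for the lists of tRNA, snRNA, snoRNA and miRNA genes.

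Translation initiation and elongation factor genes had a promoter peak in 13 of 52 cases (95% Wilson interval 15.2 to 38.2%, 2.23-fold, Fisher's exact test, adjusted p = 0.0191), the strongest at eIF6 (576.0), eEF1gamma (361.7), eIF1 (215.3) and eIF3c (185.9). Spliceosomal and other snRNA genes had one in 9 of 32 cases (28.1%, 2.50-fold, Fisher's exact test, adjusted p = 0.0205), led by snRNA:U1:95Ca (244.4), snRNA:U2:34ABb (200.1), snRNA:U1:21D (163.3) and snRNA:U4:39B (151.8). Neither of these lists kept its call among peaks found in both replicates' lists, a comparison chosen after the data were seen (1.80-fold and 1.94-fold, Fisher's exact test, adjusted p = 0.33 for both). The translation factors did not pass in the list of replicate 1 alone (1.49-fold, Fisher's exact test, adjusted p = 0.508), in the conservative list (1.83-fold, Fisher's exact test, adjusted p = 0.18) or by nearest gene (1.03-fold, Fisher's exact test, adjusted p = 0.878). By nearest gene the snRNA genes did not pass (1.89-fold, Fisher's exact test, adjusted p = 0.0793), and the snRNA genes passed in neither replicate's list (1.62-fold and 2.10-fold, Fisher's exact test, adjusted p = 0.508 and 0.173). Neighbouring genes can share 1 peak: 1 translation factor gene and 1 insulator list gene shared theirs with a ribosomal protein gene. With the strongest 500 peaks alone, the insulator list passed, with 4 of 17 genes (9.13-fold, Fisher's exact test, adjusted p = 0.023), and ribosomal protein genes, with 7 peaks, did not (2.96-fold, Fisher's exact test, adjusted p = 0.131).

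Chemoreceptor, cuticle protein, histone, tRNA, miRNA and snoRNA genes carried fewer promoter peaks, meaning summits within 500 bp of an annotated TSS, than other genes. Chemoreceptor and odorant-binding genes had one in 2 of 230 cases, at Obp99b (303.9) and Ir67c (83.2) (0.870%, Fisher's exact test, adjusted p = 9.46e-09). Cuticle protein genes had one in 0 of 118 cases (95% Wilson upper bound 3.15%, Fisher's exact test, adjusted p = 8.28e-06). The share was 2.76% for 290 tRNA genes (Fisher's exact test, adjusted p = 1.96e-06), led by tRNA:Tyr-GTA-1-8 (437.2), and 3.08% for 260 miRNA genes (Fisher's exact test, adjusted p = 1.82e-05), led by mir-9377 (345.5). It was 4.46% for 269 snoRNA genes (Fisher's exact test, adjusted p = 0.000684), where 5 of the 12 genes with a peak shared it with a ribosomal protein gene, and which came level with other genes at 1.00-fold when promoters reached 1000 bp and did not pass in the list of replicate 2 alone (0.582-fold, Fisher's exact test, adjusted p = 0.0936). The annotated start of a snoRNA gene can lie inside another gene, as that of snoRNA:Or-CD11a does in RpL28. Whether annotated starts of snoRNA and miRNA genes are where their transcripts start was not checked, so their low shares need not hold for their promoters. Histone genes had 2 peaks for 115 genes, at the replacement variants His2Av (189.4) and His3.3B (104.7) (Fisher's exact test, adjusted p = 0.000954). In the list of replicate 2 alone the share relative to other genes moved from 0.245 to 0.463 for tRNA genes, from 0.274 to 0.129 for miRNA genes, from 0.153 to 0.0965 for histone genes and from 0.0761 to 0.0479 for chemoreceptor genes, and in that of replicate 1 to 0.149 for miRNA genes, all still past the threshold. With promoters of 1000 bp it was 0.629 for tRNA genes and 0.477 for miRNA genes, and with promoters of 200 bp it was 0.132 for tRNA genes, 0.0979 for miRNA genes and 0.142 for snoRNA genes, all past the threshold. By nearest gene it was 0.347 for chemoreceptor genes, 0.58 for tRNA genes, 0.17 for cuticle protein genes, 0.058 for histone genes and 0.25 for snoRNA genes, all past the threshold. With the strongest 500 peaks none of these lists passed. Of the 115 histone genes only 7 had any ranked peak at the promoter, and among such genes the histone share was 1.98 times that of others and did not pass (Fisher's exact test, adjusted p = 0.467).

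Lists of embryonic patterning genes and cell type markers did not pass at promoters, but 7 of the 12 did when each peak was given to its nearest gene. At promoters, gap genes had 0 of 8, pair-rule genes 1 of 9, segment polarity genes 2 of 15, Hox genes 1 of 8, dorsoventral genes 1 of 21 and maternal patterning genes 1 of 12. Genes of zygotic activation and cellularization had 3 of 14. The members with the strongest promoter peaks were hry (72.1), bowl (544.2), nkd (150.9), Abd-B (83.0), sog (83.9), bcd (224.4), Trl (134.6) and smg (107.4). Among markers, neural genes had 1 of 20 (elav, 493.3), mesoderm and muscle genes 4 of 15 (tin, 360.5, and stumps, 279.3), endoderm genes 1 of 7 (fkh, 102.0), germline genes 1 of 8 (piwi, 100.2) and blood cell, tracheal and epidermal genes 2 of 11 (trh, 177.0, and ush, 133.1). Adjusted p for these 12 lists lay between 0.185 and 1.0 (Fisher's exact test), and lists this short leave wide intervals, as in 0 to 32.4% for the gap genes. By nearest gene at any distance, Hox genes had a peak in 6 of 8 cases (5.05-fold, Fisher's exact test, adjusted p = 0.000918) and pair-rule genes in 6 of 9 (4.49-fold, Fisher's exact test, adjusted p = 0.00153). Segment polarity genes and mesoderm and muscle genes each had one in 8 of 15 cases (3.596-fold, Fisher's exact test, adjusted p = 0.00153). Blood cell, tracheal and epidermal genes (4.29-fold), endoderm genes (3.85-fold) and dorsoventral genes (2.89-fold) passed as well (Fisher's exact test, adjusted p = 0.00106, 0.0219 and 0.00414). A gene's chance of a nearest peak grows with the length of DNA closer to it than to other genes, which was not adjusted for.

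Other ubiquitous gene classes did not pass at promoters either. Mitochondrial ribosomal protein genes had 13 of 73 (Fisher's exact test, adjusted p = 0.186), oxidative phosphorylation genes 8 of 86 (Fisher's exact test, adjusted p = 0.853) and proteasome genes 1 of 48 (Fisher's exact test, adjusted p = 0.0981). Signals of the 13 ranged from 70.9 at mRpL11 to 1643.2 at mRpS10. Those at mRpS10, mRpS23 (1378.1), mRpL41 (1201.7) and mRpL23 (808.0) exceeded the strongest at a cytoplasmic ribosomal protein gene (RpS27, 447.1). The peaks at mRpS10 and mRpS23 are those given above to Art3 and CenG1A, whose TSSs are nearer. By nearest gene the proteasome genes passed, with fewer peaks than other genes (0.14-fold, Fisher's exact test, adjusted p = 0.0144), and they also passed with promoters of 1000 bp. Heat shock genes had 3 of 15, Polycomb and Trithorax group genes 5 of 22 and cell cycle genes 4 of 23, with adjusted p of 0.41, 0.186 and 0.526 (Fisher's exact test).

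**Figure D3:**
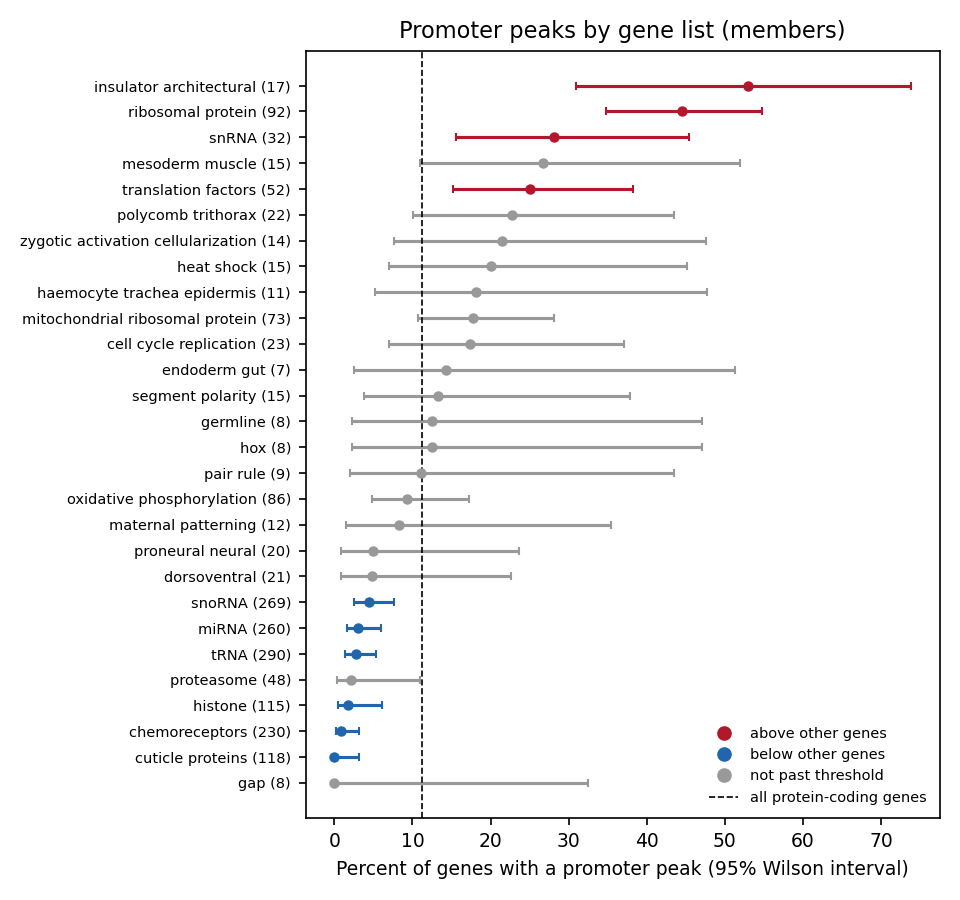
Points give the percent of each gene list with a main-list summit within 500 bp of a TSS, with 95% Wilson intervals, and numbers of members in parentheses. Red and blue lists lie above and below other genes with an adjusted p under 0.05, grey ones did not pass, and the dashed line marks the 11.3% of all protein-coding genes.

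The stronger summits lay in short A+T-rich stretches. Over the whole main list, the window from 50 bp before to 50 bp after the summit had a GC content of 37.4% ± 11.4 (SD, 3417 peaks) against 43.8% ± 10.1 in flanks of the same length 300 bp away, a mean difference of -6.335 percentage points (permutation test by sign flips, p = 0.0001, the smallest they can give). The summit was lower in 2259 peaks (66.1%). The difference was -11.0 points in the list of replicate 1 alone, -7.34 in that of replicate 2, -11.3 for main-list peaks in both lists and -13.9 for the strongest 500 peaks. The difference was -12.8 points in the strongest of the 4 signal groups, -10.8 and -4.97 in the groups between, and 3.17 in the weakest, where summits had a GC content of 45.6%. This comparison was added after the data were seen.

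**Figure D4:**
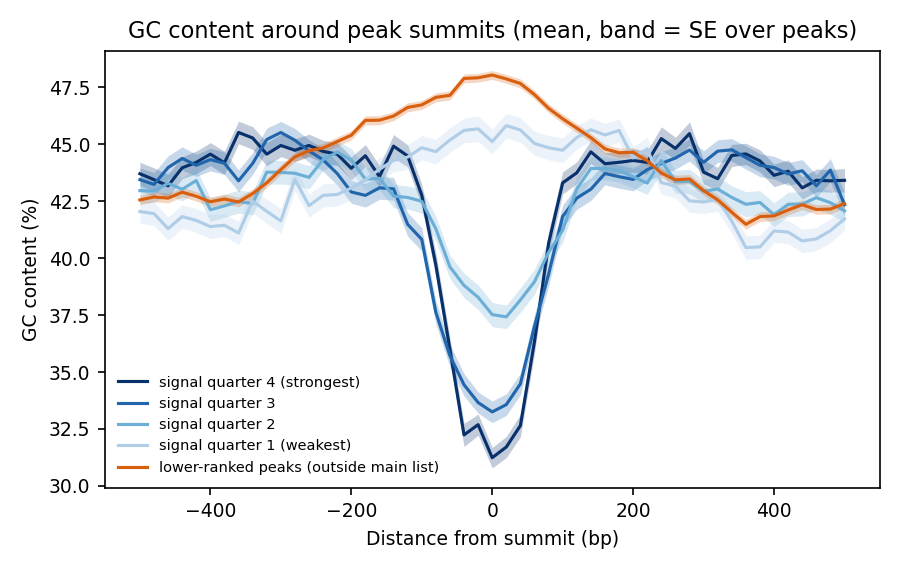
Lines give the mean GC content in windows of 21 bp by distance from the summit, in blue shades for the 4 signal groups of the main list and in orange for 5000 ranked peaks outside it, with bands of 1 SE over peaks. GC content at the summit was 31.2% in the strongest group, 45.1% in the weakest and 48.0% in the lower-ranked peaks.

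Some sequence motifs differed between summits and flanks, and fewer did against a background of like GC content. Of 19 known consensus motifs, 4 differed between summit and flank. The homeodomain core TAATTA was in 8.81% of summits and 5.68% of flanks (exact McNemar test, adjusted p = 5.7e-06), and the GATA site in 19.5% and 15.7% (exact McNemar test, adjusted p = 0.000213). The GAGA element was in 10.6% and 15.2% (exact McNemar test, adjusted p = 1.18e-07). The core of the CTCF site, bound by the insulator protein CTCF, was in 3.86% of summits and 2.40% of flanks (exact McNemar test, adjusted p = 0.00306). Against lower-ranked summits matched on GC content, a background chosen after the data were seen, TAATTA, GATA and GAGA did not pass (0.855, 1.10 and 1.11-fold, exact McNemar test, adjusted p = 0.109, 0.13 and 0.354). The CTCF core did (2.20-fold, exact McNemar test, adjusted p = 2.59e-06), and so did Ohler motif 7, a core promoter element (3.22-fold, exact McNemar test, adjusted p = 4.48e-05). That background was not matched on location. Promoters held 39.1% of main-list summits and 13.6% of draws from ranked-list summits outside that list. Ohler motif 7 did not pass against flanks (1.61-fold, exact McNemar test, adjusted p = 0.076). Against flanks, the CTCF core did not pass in the list of replicate 1 (1.23-fold, exact McNemar test, adjusted p = 0.382) or among the strongest 500 peaks (1.11-fold, exact McNemar test, adjusted p = 1.0). Among those 500, also against flanks, TAATTA was at 2.70-fold and GAGA at 0.408-fold (exact McNemar test, adjusted p = 0.000161 and 3.53e-06). Summits of those 500 differed from their flanks by -13.9 points of GC content, and no GC-matched comparison was run for them.

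The 8-mers found on 2L and 2R were made of A and T for the most part. Of 10 tested on the 2171 peaks of 3L, 3R and X, 8 passed, led by ATATTAAA in 3.87% of summits and 0.783% of flanks (exact McNemar test, adjusted p = 4.39e-11). A new ranking on 2L and 2R against the GC-matched background gave another 10, of which 4 passed on 3L, 3R and X. AGATGGCG was in 33 summits and 1 matched window (exact McNemar test, adjusted p = 4.07e-08) and GATGGCGC in 30 and 2 (exact McNemar test, adjusted p = 1.23e-06). AGGGTTAA was in 38 and 12 (exact McNemar test, adjusted p = 0.000556) and CACTGAGA in 29 and 5 (exact McNemar test, adjusted p = 0.000129). Each of these 4 was in fewer than 2% of the peaks tested. AGATGGCG is 1 form of the CTCF core consensus, and GATGGCGC is the same word shifted by 1 base, so both can mark the same sites as that motif.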

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

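Of the main-list peaks, 17 lay outside the arms used in the comparisons, 1 on the Y chromosome at 975728 to 976087 with a signal of 108.0, and the others on unplaced scaffolds assigned to the X chromosome, with a highest signal of 377.4. They stand out because the comparisons leave them out although they passed the authors' threshold.

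A further 115 peaks of the ranked list had a score as high as the main list's lowest, yet the main list leaves them out, 84 of them on the arms. The strongest lay at 2L 480923 to 481253, in an intron of ush, 1400 bp upstream of a TSS of cbt, with a signal of 1736.77 that only 4 main-list peaks exceeded. Others lay at 3R 11760894 to 11761190 in an intron of Lk6 (signal 1413.32) and at 3R 28326470 to 28326745 in larp (signal 896.128). No biological explanation was tested for either group of peaks.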

How the results depend on the processing

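The tests with GC matching, with close peaks merged, with peaks in both replicates' lists, and all those of GC content were chosen after the data were seen. The promoter excess, the overlap of the replicates and the lower GC content at summits kept their direction and passed under each of the 9, 5 and 6 alternatives run for them, at 2.12 to 4.49-fold, 53.7 to 79.8% and -13.9 to -7.02 points. The Spearman correlation was 0.817 for summits within 100 bp and 0.718 for the main list matched in the ranked lists. With the strongest 500 peaks, 2 arms passed instead of 4, 1 gene list instead of 10, and the promoter signal difference was 22.7 and did not pass, with fewer peaks tested. There, 3L turned to 0.914-fold and snRNA genes to 0-fold. The snoRNA list turned to 1.00-fold with promoters of 1000 bp, and histone genes to 1.98-fold among genes with a ranked peak. Known motifs past the threshold numbered 4 in the main comparison, 7 in the conservative list, 9 with 100 bp on each side, 9 against ranked-list summits, 2 against GC-matched ones, and 5 to 7 in the single replicates. Against the GC-matched summits, which also replaced the flanks, GAGA turned to 1.11-fold and TAATTA to 0.855-fold, and a new ranking gave 4 8-mers past the threshold instead of 8. By nearest gene 15 lists passed, 8 of them lists that did not pass at promoters, while the insulator list (1.98-fold), snRNA genes (1.89-fold) and translation factors (1.03-fold) did not. The cause of these changes was not tested. The setting with the strongest 500 peaks changed both the number of peaks and which peaks were tested. Depth is unknown, so it sets no stated limit on weak peaks. No paired analysis was possible because there is only 1 group.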

Other observations

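All tests in this part were chosen after the results they bear on were seen. No biological explanation was tested, since the design has 1 group.

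The low GC content of the stronger summits, those in the upper 2 of the 4 signal groups, was set against technical explanations. For a bias of amplification or sequencing towards A+T-rich DNA, weak peaks were examined. The 140697 ranked peaks that overlap no main-list peak were higher in GC content at the summit than in the flank, by 4.41 percentage points (SE 0.033). This cannot decide against such a bias, because peaks were sorted by the signal it would raise, which would leave the most A+T-rich sites at the top. Location at promoters did not account for all of the pattern. The 785 stronger promoter summits were -7.26 points (SE 0.49) from positions at the same distance from randomly drawn TSSs, and the 923 stronger distal summits were -12.1 points (SE 0.45) from their flanks. No binding preference was tested, and the origin of the pattern stays open.

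Peaks at ribosomal protein gene promoters could come from a general ChIP signal at ubiquitously transcribed genes. Oxidative phosphorylation, proteasome, mitochondrial ribosomal protein and translation factor genes, pooled, had a promoter peak in 13.5% of 259 cases (95% Wilson interval 9.88 to 18.2), against 44.6% of ribosomal protein genes (Fisher's exact test, p = 5.39e-09) and 11.0% of the remaining genes (Fisher's exact test, p = 0.193). An earlier pool of the first 2 of these classes, which gave 6.72%, was set aside because they had been chosen after their low shares were seen. The values leave no room for an equal share in the 4 classes and the ribosomal protein genes, but a smaller effect, as in translation factor genes (13 of 52, Fisher's exact test against the remaining genes, p = 0.00576), stays open. Transcript levels were not analysed here, so an effect limited to the most highly transcribed genes stays open as well.

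The peaks on both sides of CG10959 may come from extra copies of the locus in the transgenic strain, which could raise signal over a block of DNA. The signal is relative to a control, so copies present in the control as well would not raise it in the same way. The controls were not analysed here, so whether this applies is unknown. The median ranked signal within 10 kb of the gene's midpoint, 40.6 over 25 peaks, lay at percentile 99.4 of the values around 2148 other protein-coding genes of the X chromosome. In windows of 10 kb it was 41.4 and 40.6 on either side of that midpoint, and 18.5 and 25.4 in the windows beyond. The 25 ranked peaks include the main-list peaks that prompted the comparison, so the percentile in part restates them. Binding of the protein near its own gene could raise these values as well and is not excluded, and the extent of the inserted DNA is not given in the sources used here.

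Each of the 95 main-list peaks with a signal under 20 lay within 500 bp of a main-list peak above 20, at a median of 204 bp, and for 60 of them that neighbourhood held a peak with at least 10 times the signal. Summits in annotated transposable elements numbered 13 (0.38%), against 1.28% of the 140697 ranked peaks that overlap no main-list peak (Fisher's exact test, p = 9.72e-08). Such elements hold 5.73% of positions by length, but how many reads can be placed in them was not measured.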
